A study of Mus musculus with 3 samples.

How the data were processed

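Small RNA was sequenced from HL-1 cells, a mouse cardiac muscle line that keeps contracting in culture, harvested 48 h after transfection with siRNA (9 µl of a 20 µM stock per well, per the labels). The samples carry 3 titles, for an unspecific siRNA (siNon) and for a pair of siRNAs against Srf (siSrf1 and siSrf2). Values for the libraries titled siSrf1 and siSrf2 were used, and the library titled siNon was not analysed here. The titles and the siRNA entry of the same samples disagree: the sample titled siSrf1 carries the entry Srf si2, and the sample titled siSrf2 carries the entry siNon. Groups follow the titles, so every direction refers to "the library labelled siSrf1" or "the library labelled siSrf2". There was 1 library per group.

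The authors deposited, for each library, a count of reads for every distinct sequence, without normalization, per the description deposited with the series. Libraries were made with an Illumina small RNA kit and run on the Genome Analyzer, per the labels. All sequences were 36 nt long and still held the 3' adapter TCGTATGCCGTCTTCTGCTTG. An aligner, a genome build and a read filter are not given in the sources used here.

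Each read was searched for the first 8 nt of the adapter without mismatch, or for a shorter match of at least 4 nt at the read end, and the part before it was kept as the insert if it had 15 nt or more and no N. Inserts of 18 to 25 nt were matched without mismatch to both strands of the NCBIM37 mouse genome with a search written for this purpose (Python 3.11.15, numpy 2.4.6, numba 0.67.0, pysam 0.24.0). Hairpins came from the GENCODE vM1 annotation of that genome. They were named through RefSeq gene symbols (assembly GRCm38.p6, used for names and gene order only): 527 by symbol or synonym and 115 by their place beside a gene named in both. Naming by place, tried on 487 genes named in both, gave the right gene for 446, no gene for 30 and another gene for 11. An miRNA is an arm of a named hairpin defined by its most frequent insert. An insert counted if it matched the hairpin exactly, with its start within 2 nt and its end within 3 nt of that insert. Inserts that fitted several miRNAs were shared equally between them, so miR-133b with miR-133a, and miR-107 with miR-103, are uncertain. Members of the let-7 family differ by few bases, and sequencing errors can move reads between them.

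Reads were scaled to the total of miRNA reads. The log2 ratio is siSrf1 minus siSrf2 with a pseudocount of 0.5 reads, for miRNAs with at least 50 reads summed over both libraries, and its exact binomial 95% interval is conditional on the sum of both counts. An miRNA was past the size rule if the libraries differed by at least 2-fold and the whole interval lay on 1 side of 0. Shares carry exact Clopper-Pearson 95% intervals and single counts exact Poisson intervals (scipy 1.17.1, pandas 2.3.3). Reads without molecular identifiers are not independent molecules, and with 1 library per group there is no replicate check. Intervals of read counts, shares of reads and their ratios therefore cover counting error only, and no p-value was computed. Intervals over numbers of miRNAs, used in tests of explanations, treat miRNAs as independent, which they need not be. For 22 lists of miRNAs the member was the arm with the most reads. A list's median was placed among 10000 random lists of the same size, each member replaced by 1 of the 20 miRNAs nearest in abundance, if at least 3 members were measured.

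The miRNAs named are the 10 with the highest mean abundance, the 8 with the largest ratio in each direction among those past the size rule with at least 200 reads, the measured members of the muscle list and of the list with published SRF control, and up to 4 of the most abundant members of any other list. Any other miRNA named was chosen after its values were seen. The lists, the size rule, the naming rule and most alternatives were fixed before the data were examined. Alternatives were TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0, R 4.3.3), totals of all inserts of 15 nt or longer, totals without the 5 most abundant miRNAs, minimums of 10 and 500 reads, inserts of 20 to 24 nt and 16 to 28 nt, 12 nt of adapter, 1 mismatch, inserts with several matches left out, sequences seen once left out, and a pseudocount of 5 reads. A total without miR-1a-3p, 12 nt of adapter with 1 mismatch, and the count of both arms in a list were added after the data were seen. Several tests of explanations were likewise set or altered after their values were seen, and the removals of a trend, the test of GC over other inserts and the test of carry-over, each run in 2 forms, are given in both.

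The steps were tested on simulated data. Counts for the 230 measured miRNAs were drawn from their real abundance in 50 rounds, with 20 miRNAs changed per fold size. The size rule called 98.5% of those changed 3-fold and 100% of those changed 6-fold in the right direction, 2.85% of those changed 1.5-fold, and 0.108% of unchanged ones. The interval held the true log2 ratio in 95.8% of cases. A first run gave a lower coverage, and the true ratio was then redefined on the scale of the library totals. This coverage therefore does not test the choice of scaling. The rates of calls and the coverage describe simulated counts and need not hold for the real libraries. Of 20000 simulated reads, 99.995% were trimmed to the right length, and 120 inserts gave the same number of matches on chromosome 19 by plain text search. Figures were drawn with matplotlib 3.10.9.

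The depth was 14911499 reads in the library labelled siSrf1 and 14518157 in the library labelled siSrf2. Sequences without a match to the genome are reported as totals only.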

Results

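Small RNA libraries of HL-1 cardiomyocytes, made after siRNA against Srf by their titles, were compared with each other. Srf encodes serum response factor, a transcription factor of muscle genes, and without a control library the comparison cannot show which miRNAs depend on it. The libraries analysed carry the titles siSrf1 and siSrf2, with 1 library each. By title both received an siRNA against Srf, while by the siRNA entry of the same samples the library labelled siSrf1 received Srf si2 and the library labelled siSrf2 the unspecific siRNA. Of 14911499 and 14518157 reads, 59.4% and 57.2% held an insert of 15 nt or longer. No adapter was found in 32.6% and 31.8%, and the insert had a length of 0 nt in 6.51% and 8.35%.

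Reads of transfected siRNA were found in both libraries and served as a check of the labels. A duplex register of Srf at mRNA positions 1878 to 1901 was read 1230 times in the library labelled siSrf2 (exact Poisson interval 1162 to 1301), with 1053 sense and 177 antisense reads, and 19 times in the library labelled siSrf1 (11.4 to 29.7). A further duplex at positions 2111 to 2131 was read 17 times in the library labelled siSrf1 (9.90 to 27.2), with 2 sense and 15 antisense reads. It was read 0 times in the library labelled siSrf2, which allows up to 3.69 reads. Both sites lie in the 3' UTR of Srf, in exon 7, on the minus strand of chromosome 17 (NCBIM37), at 46685980 to 46686003 and 46685750 to 46685770. The most frequent sequence of the first site was ACGGCACCACTTATTTATT with 716 reads in the library labelled siSrf2, and that of the other site was AATACTCATAGCAAATTGAG with 9 reads in the library labelled siSrf1. Reads of an Srf duplex in the library labelled siSrf2 go against its siRNA entry siNon, and these reads do not settle which duplex is si1 or si2. The Srf mRNA itself is not measured by this assay, so the depth of the knockdown is unknown.

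miRNAs made up 63.2% (63.1 to 63.2) of the 7748874 inserts of 18 to 25 nt in the library labelled siSrf1 and 59.9% (59.9 to 59.9) of 7013026 in the library labelled siSrf2. Fragments of other RNAs took a larger share in the library labelled siSrf2. Mitochondrial tRNA, which serves translation inside mitochondria, was 4.31-fold higher there (542 and 2114 reads), and snoRNA, which guides modification of ribosomal RNA, was 3.10-fold higher (2347 and 6576 reads). Inserts with a single genome match, in a protein-coding exon in sense, were 2.53-fold higher (4432 and 10150 reads). They need not be mRNA fragments, since frequent ones in Hspa8 and Gss nearly equal a snoRNA and a many-copy sequence. Those in Gys1 (48 and 102 reads) and Hspa8 (28 and 56) were higher there, those in Gss (38 and 33) and Lars2 (38 and 32, 30 and 21) were not. The 5' adapter sequence was 2.67-fold higher (17415 and 42107 reads). Ribosomal RNA was 1.15-fold higher (30363 and 31553 reads), but an 18 nt 5S fragment had 535 and 385 reads. The remaining genome matches, with more reads than these classes, were 1.64-fold higher (219481 and 325829 reads). Inserts of 22 nt, the usual length of miRNAs, were 59.0% (58.9 to 59.0) of all inserts of 15 nt or longer in the library labelled siSrf1 and 52.0% (52.0 to 52.1) in the library labelled siSrf2. No match to the genome or to a miRNA with 1 mismatch was found for 23.3% and 24.1% of inserts of 18 to 25 nt, and their origin, the mouse or another source, was not settled.

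**Figure D1:**
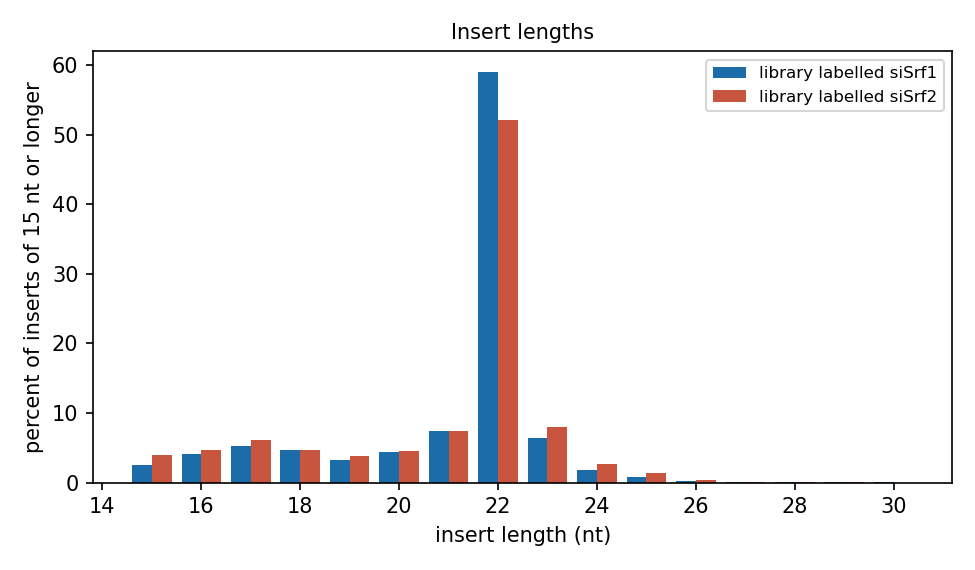
Bars give the percent of inserts of 15 nt or longer (vertical axis) at each insert length in nt (horizontal axis), for the libraries labelled siSrf1 and siSrf2. The peak at 22 nt holds 59.0% and 52.0% of inserts, and lengths of 23 nt hold 6.35% and 7.96%.

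The miRNA pool of both libraries was dominated by miR-1a-3p, the most abundant miRNA of striated muscle. It made up 65.6% of miRNA reads (65.5 to 65.6) in the library labelled siSrf1 and 54.7% (54.6 to 54.7) in the library labelled siSrf2, a log2 ratio of 0.26 (0.26 to 0.26). Its sequence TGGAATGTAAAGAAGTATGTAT lies in the hairpin Mir1a-1 on chromosome 2, 180123801 to 180123822. The first 18 nt match the genome at 3 places, so the reads need not all come from this hairpin. The let-7 members let-7f-5p, let-7c-5p, let-7a-5p, let-7b-5p and let-7g-5p, which restrain growth and keep cells differentiated, followed with 7.65%, 4.34%, 3.83%, 2.38% and 1.04% in the library labelled siSrf1. The other abundant miRNAs were miR-199a-3p with its identical copy miR-199b-3p (1.60% and 1.34%), miR-499-5p, encoded within a myosin heavy chain gene (1.44% and 1.45%), miR-378a-3p, encoded within Ppargc1b (1.31% and 1.38%), and miR-103-3p (0.873% and 1.02%). The 10 most abundant together held 90% and 86.1% of miRNA reads.

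Of 230 measured miRNAs, 56 were higher in the library labelled siSrf2 past the size rule and 1 in the library labelled siSrf1, while 173 were not past it. Among those past the rule with at least 200 reads, the furthest were miR-345-5p with 33 and 272 reads (9.48-fold, log2 ratio -3.24, interval -3.83 to -2.74), miR-351-3p with 29 and 174 reads (6.89-fold, log2 ratio -2.79, interval -3.43 to -2.23) and miR-145a-5p, an miRNA that promotes the smooth muscle program, with 579 and 2431 reads (4.89-fold, log2 ratio -2.29, interval -2.42 to -2.16). The next at this depth were miR-187-5p (log2 ratio -2.02), miR-501-3p (-1.93), miR-484-5p (-1.91), miR-25-5p (-1.85) and miR-1981-5p (-1.77), all higher in the library labelled siSrf2, and some miRNAs with fewer reads lay further apart. These 8 had a GC content from 52.2% (miR-145a-5p) to 68.2% (miR-187-5p), and miR-1a-3p had 27.3%. Over the 230 miRNAs Spearman's rho of the log2 ratio with GC content was -0.23. Not all GC-rich miRNAs went this way: miR-486a-5p and miR-210-3p, both at 63.6%, lay at 0.20 and 0.15. On the siSrf1 side the single call was miR-132-3p, an miRNA linked to cardiac hypertrophy, with 42 and 14 reads (2.52-fold, interval of the log2 ratio 0.46 to 2.35), named here after its values were seen, and with 1 mismatch allowed it was no longer past the rule.

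The split of calls depends on the scaling. The median log2 ratio of all miRNAs was -0.44 scaled to the miRNA total, with 185 below 0 and 45 above. TMM factors moved it up by 0.54 and gave 30 miRNAs higher in the library labelled siSrf2 and 4 in the library labelled siSrf1, so that the siSrf1 side held 11.8% of calls against 1.75%. The move of 0.54 left each of the 8 named above on the siSrf2 side at least 2-fold apart, with miR-1981-5p closest at a log2 ratio of -1.23.

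**Figure D2:**
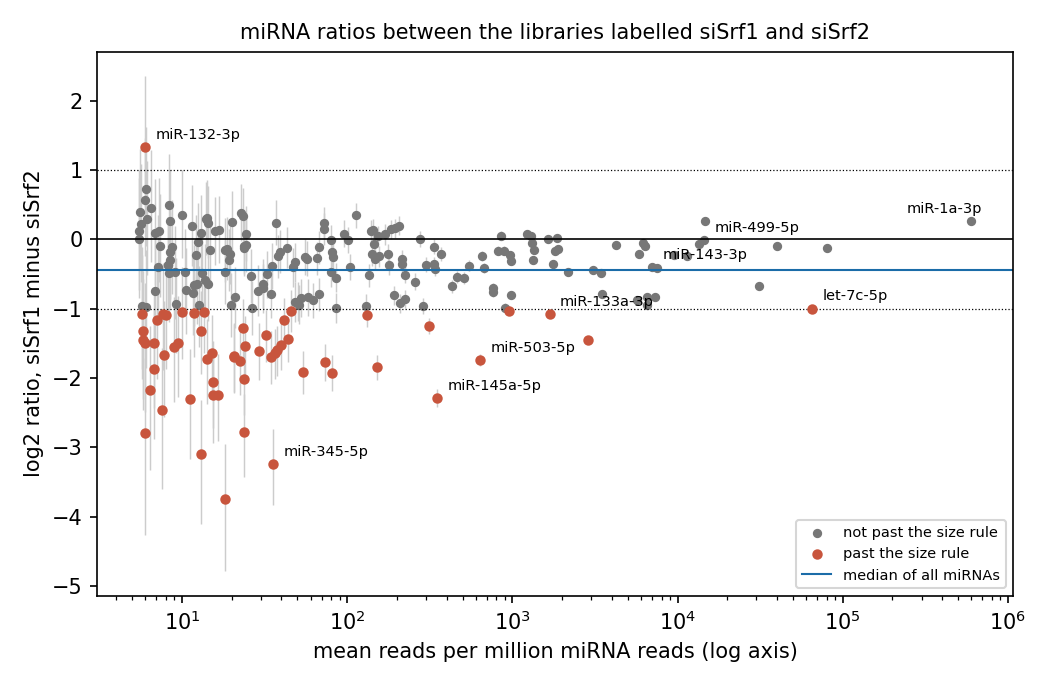
Each point is 1 of 230 miRNAs, with its mean abundance scaled to the miRNA total on a log axis and its log2 ratio (siSrf1 minus siSrf2) on the vertical axis. Bars are exact 95% intervals that cover counting error only, dotted lines mark 2-fold, and the median line lies at -0.44, below 0, which TMM factors move to 0.10.

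Among miRNAs with published control by SRF, ratios went both ways. miR-145a-5p was lowest in the library labelled siSrf1, and miR-133a-3p, which restrains growth of cardiomyocytes, was also lower there, with 5282 and 9577 reads (2.11-fold higher in the library labelled siSrf2, log2 ratio -1.08, interval -1.13 to -1.03). The other arm, miR-133a-5p, had 948 and 988 reads, a 5p share of 15.2% (14.3 to 16.1) and 9.35% (8.80 to 9.92). miR-143-3p, transcribed with miR-145a, had 29789 and 33669 reads and a log2 ratio of -0.40 (-0.42 to -0.37), and miR-1a-3p was the only member of the 4 above 0. With TMM factors miR-133a-3p was no longer 2-fold apart (-0.54), and miR-143-3p turned to 0.14. The list median was -0.74, at percentile 6.35 of random lists, and -0.20 with TMM factors.

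The muscle list had 8 of 9 members measured, with 1 past the size rule, miR-133a-3p. miR-133b-3p lay at -0.97, miR-208a-5p, encoded within a cardiac myosin gene, at -0.90 (its other arm, miR-208a-3p, at 0.45, interval -0.32 to 1.28), miR-208b-3p at -0.28, miR-499-5p at -0.01, miR-378a-3p at -0.07 and miR-486a-5p at 0.20. The median was -0.17 at percentile 86.6, and it turned to 0.37 with TMM factors and 0.27 with median-of-ratios factors. miR-206, of skeletal muscle, had 15 and 10 reads.

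The let-7 family lay below 0 in each of its 9 members, with a median of -0.68 at percentile 0.240 of random lists. let-7c-5p was the single member past the rule (4.34% and 8.69% of miRNA reads, interval of the log2 ratio -1.01 to -0.99), let-7b-5p lay at -0.68 and let-7e-5p at -0.95, while let-7a-5p and let-7f-5p were nearly level at -0.10 and -0.13. With TMM factors the family median stayed below 0 at -0.14, let-7c-5p was no longer past the rule at -0.46, and let-7a-5p, let-7f-5p, let-7g-5p and let-7i-5p turned above 0. The cluster of miR-322, miR-503 and miR-450 on the X chromosome, which slows the cell cycle, was below 0 in each of 6 members, with a median of -0.96 at percentile 11.8 and 3 members past the rule, miR-503-5p (1438 and 4130 reads, log2 ratio -1.74), miR-542-3p (-1.64) and miR-351-5p (-1.16), and miR-322-3p at -0.77. Its median with TMM factors was -0.42, and miR-351-5p was then no longer past the rule (-0.62). The miR-30 family, abundant in heart muscle, had a median of -0.83 at percentile 6.37 with 5 of 5 members below 0, among them miR-30d-5p (-0.88), miR-30c-5p (-0.92), miR-30a-5p (-0.48) and miR-30e-3p (-0.38), and -0.29 with TMM factors, which put miR-30a-5p and miR-30e-3p above 0. miR-30e entered by its more-read 3p arm, whose sequence starts unlike the 5p arms named, and its 5p arm had 1836 and 2300 reads. In the cluster of miR-183, miR-96 and miR-182 both measured members were past the rule, miR-182-5p at -1.09 and miR-183-5p at -1.03, but with TMM factors neither was (-0.55 and -0.49), and the median was -0.52. miR-34c-5p, the measured member of the p53-linked list, lay at -0.79.

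The Dlk1-Dio3 imprinted cluster stood at the opposite end, with 11 members measured of 39, none past the rule and a median of 0.25 at percentile 100, and with TMM factors 1 past the rule on the siSrf1 side and a median of 0.79. Its most abundant members were miR-127-3p at 0.35, miR-411-5p at 0.38, miR-495-3p at -0.13 and miR-543-3p at 0.25. The cardiac stress list, 13 of 14 measured, had a median of -0.01 at percentile 100, with miR-21a-5p at -0.10, miR-29a-3p at -0.20, miR-199a-3p/miR-199b-3p at 0.26 and miR-132-3p as the single member past the rule, and it turned to 0.53 with TMM factors. In the hypoxia and inflammation list miR-210-3p lay at 0.15, miR-146a-5p at 0.12 and miR-146b-5p at -0.79, with a median of 0.12 at percentile 96.5, and 0.66 with TMM factors.

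In the following families the median was below 0 when scaled to the miRNA total and above 0 with TMM and median-of-ratios factors. The miR-17 to 92 list and its paralogs had 7 members measured and a median of -0.22 (percentile 72.8), with miR-25-3p at -0.45, miR-92a-3p at -0.22, miR-93-5p at -0.52 and miR-106b-5p at -0.28. The miR-15/16 family had a median of -0.19 (percentile 90.9), with miR-15b-5p at -0.99, miR-16-5p at -0.21 and miR-497a-5p at 0.05. This median includes miR-322 by its more-read 3p arm, whose sequence starts unlike those 5p arms, while its 5p arm had 87 and 148 reads. The list of miR-23, miR-24 and miR-27 had a median of -0.14 (percentile 97.1), with miR-27b-3p at -0.14, miR-24-3p at -0.17, miR-23a-3p at 0.04 and miR-27a-3p at 0.05. The miR-29 family had a median of -0.20 (percentile 63.0), with miR-29c-3p at 0.07 and miR-29b-3p at -0.38, and the pair of miR-221-3p (-0.08) and miR-222-3p (-0.55) a median of -0.32. Each member stood for its most-read arm, and none of these arms was past the rule. Other arms of the same hairpins lay further apart. miR-25-5p was past the rule (321 and 992 reads, log2 ratio -1.85), while miR-17-3p had 11 and 44 reads and miR-23a-5p 18 and 78.

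Lists of other cell types held both rare and abundant miRNAs. miR-126a-5p of endothelium had 1013 and 778 reads and lay at 0.16. Of 6 miRNAs of blood cells 3 were measured, miR-142a-5p (-0.39), miR-223-3p (-0.08) and miR-451a-5p (-0.14), with a median of -0.14 at percentile 89.0, which turned to 0.40 with TMM factors. Of the neuronal list miR-128-3p (-0.37) and miR-9-5p (-0.15) were measured, with a median of -0.26 that turned to 0.28. Of liver and pancreas miR-122-5p was measured, with 32 and 57 reads at -1.04, past the rule, but not with TMM factors (-0.50). The fibroblast and smooth muscle list held miR-145a-5p, miR-143-3p, miR-199a-3p/miR-199b-3p and miR-214-3p (0.31), with a median of -0.07 at percentile 96, which turned to 0.47. None of the 7 epithelial miRNAs reached 50 reads, their hairpins holding 74 reads together, and the hairpins of the 6 miRNAs of the miR-290 cluster of embryonic stem cells held 0 reads.

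**Figure D3:**
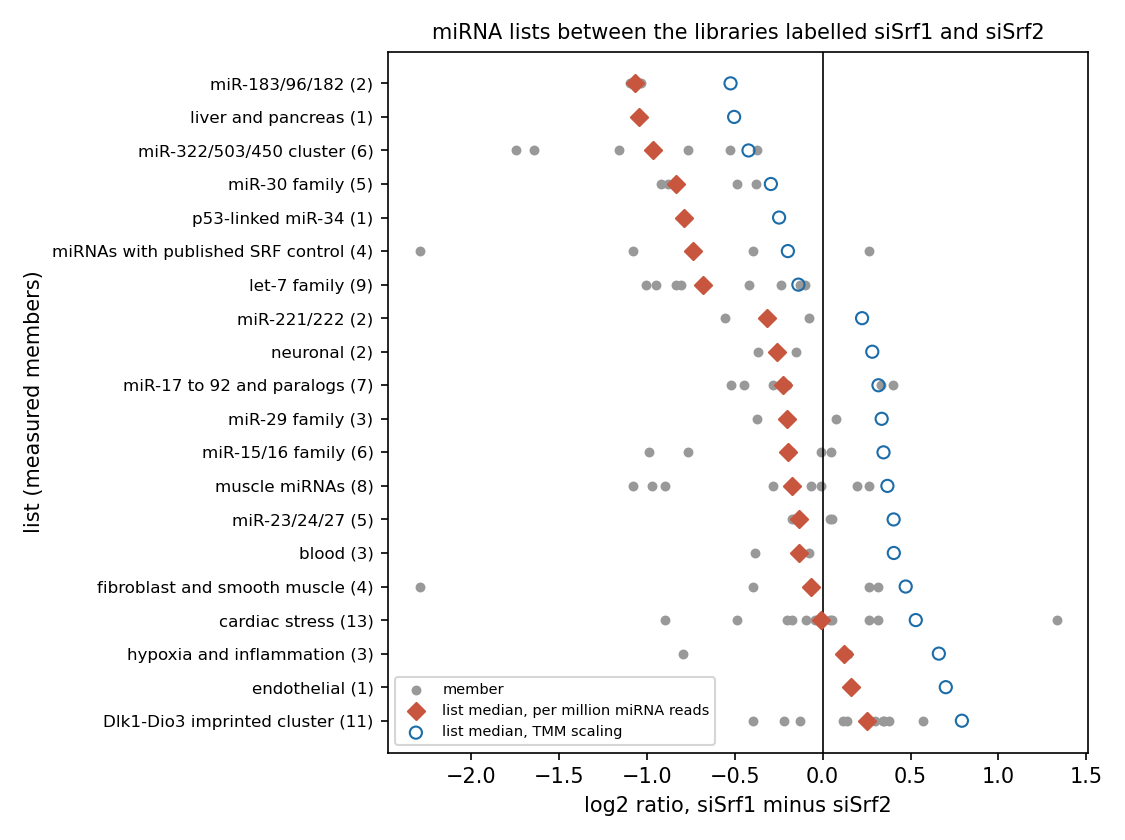
Grey points are the log2 ratios (siSrf1 minus siSrf2) of the measured members of each list, diamonds the list median scaled to the miRNA total, and open circles the median with TMM factors. The let-7 family lies at -0.68 and -0.14, and the muscle list turns from -0.17 to 0.37.

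Ends and arms of miRNAs were compared at read level. Among 72 hairpins with both arms measured, the 5p share differed by 10 points or more with intervals apart in 7. miR-345 read 24.8% (17.7 to 33.0) from its 5p arm in the library labelled siSrf1 and 52.3% (47.9 to 56.7) in the library labelled siSrf2, miR-3102 79.7% (67.2 to 89.0) and 48.0% (42.0 to 54.1), miR-351 81.2% and 58.0%, miR-17 89.0% and 66.7%, miR-187 21.8% and 37.9%, miR-106b 59.8% and 48.4%, and miR-151 76.5% and 65.0%. These hairpins were named because the count was small, after their values were seen. The 5' end was alike in both libraries: over 106 miRNAs a median of 99.0% of reads in each began at the main 5' end, and in 0 of them did this share differ by 5 points. Some miRNAs had a variable 5' end in both, chosen after their values were seen, such as miR-126a-3p (46.1% and 46.8% at the main end), miR-101a-3p (50.8% and 50.9%) and miR-133a-3p (58.6% and 57.5%). Reads with an untemplated 3' A had a median of 6.54% and 6.86% and those with an untemplated 3' T 3.96% and 3.53%. With intervals apart, an untemplated A was more frequent in 9 miRNAs in the library labelled siSrf1 and in 6 in the library labelled siSrf2, among them let-7c-5p (5.51% and 7.22%), and an untemplated T in 8 and 3. miR-24-3p, with 51.6% (50.9 to 52.3) and 51.5% (50.8 to 52.2) of reads ending in an untemplated T, was alike in both libraries.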

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

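The search that gave these values was chosen after the adapter shares had been seen. Outside the comparisons, 293362 reads of the library labelled siSrf1 and 215002 reads of the library labelled siSrf2 began with the sequence of miR-1a-3p but held no adapter match. They are 1.97% and 1.48% of all reads and did not enter the counts. The reads counted for miR-1a-3p were also more in the library labelled siSrf1, 3208769 against 2297432. The shares of all reads therefore need not mean an unlike loss between the libraries. No biological explanation was tested for the reads without an adapter match.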

How the results depend on the processing

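The total without miR-1a-3p, 12 nt of adapter with 1 mismatch and the count of both arms were chosen after the result was seen. No paired analysis was possible because each group has 1 library. The direction of the 16 named miRNAs past the size rule was the same under each alternative that gave a value, while 29 of the others changed sign under some alternative, 27 of them with TMM factors. For the 16, no scaling could have changed the direction. The rule took them at least 2-fold apart, and the largest move, with TMM factors, was 0.54. The number higher in the library labelled siSrf2 was 56 and became 30 with TMM factors, 37 with median-of-ratios factors and 11 with at least 500 reads, which leaves fewer miRNAs. On the siSrf1 side 1 became 4, 3 and 0 in the same order, 2 with the 5 most abundant left out of the total, 2 with miR-1a-3p left out and 0 with 1 mismatch, where miR-132-3p was lost. In miRNA lists between libraries: muscle miRNAs had a median of -0.17, which became 0.37 with TMM factors, 0.27 with median-of-ratios factors, 0.15 without the 5 most abundant and 0.22 without miR-1a-3p, -0.0448 with totals of inserts of 15 nt or longer, -0.0650 with at least 10 reads and with at least 500 reads, and -0.0577 with 1 mismatch. The median of miRNAs with published SRF control of -0.74 became -0.20, -0.30, -0.41 and -0.34 under the first 4 of these scalings, -0.61 with totals of inserts, -0.69 with 1 mismatch and -0.41 with both arms. A scaling moves each miRNA by the same amount, and for the other alternatives the cause was not tested. For library composition: percent of inserts that are miRNA, siSrf1 gave 69.8% at 20 to 24 nt, 56.9% at 16 to 28 nt, 65.1% with 12 nt of adapter and 72.0% without sequences seen once, and for library composition: percent of inserts that are miRNA, siSrf2 the values were 67.5%, 52.8%, 61.7% and 69.1%. The share of 22 nt was 59.7% and 52.6% with 12 nt of adapter. In the label check by siRNA strands: reads of the Srf duplex at mRNA position 1878, siSrf2 came to 261 at 20 to 22 nt and 1693 with 1 mismatch, and the duplex at 2111 had 35 with 1 mismatch in the library labelled siSrf1. Under alternatives 217 list values stayed within counting error and 100 moved, and for named miRNAs 687 stayed and 296 moved. With at least 500 reads several lists of few reads (blood, liver and pancreas, and miR-34) and rare named miRNAs gave no value. Depth limits miRNAs near 50 reads, such as miR-132-3p with 56, whose intervals span more than 2-fold.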

Other observations

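The test without miR-1a-3p, both removals of a trend, both tests of the siRNA reads and the comparison at 21 nt were chosen after the result was seen, and 2 other tests had conditions added after their values were known, as stated with them. The demand that a ratio's whole interval clear the bound of 3 was set after 3.44 was known for GC content, a value that by the bound alone would have argued against GC bias as the whole cause, and the demand that both tests of the siRNA reads go the same way was set after both were known.

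Some fragments of other RNAs lay far apart between the libraries, and those given here were picked for their size after their values were seen. A 24 nt fragment of the mitochondrial ribosomal RNA mt-Rnr2 (ACTAATCCTAGCCCTAGCCCTACA, chromosome M, 1094 to 1117) had 92 and 872 reads, 10.4-fold higher in the library labelled siSrf2 (log2 ratio -3.38, interval -3.71 to -3.08). A 20 nt fragment of the spliceosomal RNA U2 had 23 and 418 reads (19.7-fold, and 52.6-fold at 19 nt), a 24 nt fragment of a Y RNA 91 and 599 reads (7.24-fold, while fragments of 20 to 23 nt from another Y RNA place ranged from 0.966-fold at 20 nt to 2.15-fold at 23 nt), an 18 nt fragment shared by Snord14c and Snord14d 247 and 571 reads (2.55-fold, and 94 and 555 reads at 19 nt) and an 18 nt fragment of the mitochondrial tRNA mt-Tq 16 and 178 reads (12-fold). Fragments of the spliceosomal RNA U1 did not share this direction: a 20 nt one had 66 and 52 reads (log2 ratio 0.20, interval -0.35 to 0.75).

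The arm read less often in the library labelled siSrf1 was, for several hairpins, among the miRNAs furthest apart, also chosen after seeing the values. miR-3102-3p had 12 and 143 reads (13.4-fold higher in the library labelled siSrf2), miR-23a-5p 18 and 78 reads (4.94-fold) and miR-17-3p 11 and 44 reads (4.51-fold), while the other arm of miR-23a, miR-23a-3p, lay at 0.04. Their direction follows in part from this choice. Other less-read arms were nearly level, such as miR-22-5p (851 and 695 reads) and miR-30a-3p (2926 and 2960 reads). Among abundant miRNAs outside the naming rule, miR-423-5p had 7489 and 17578 reads (2.74-fold) and miR-744-5p 3066 and 5370 reads (2.04-fold), and neither stayed 2-fold apart with TMM factors.

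Of the 57 miRNAs past the size rule 56 lay on the siSrf2 side. Leaving miR-1a-3p out of both totals left 38 against 2, a ratio of 19 (exact interval 4.91 to 163). This argues against its larger share of reads as the whole cause. That total still moved the median from -0.44 to -0.04 and the siSrf2 side from 56 to 38. Removing a linear trend on insert length on that scale left 35 against 1, a ratio of 35 (5.88 to 1421). This removal shifted no log2 ratio by more than 0.52, so the split had little room to change. It shows only that a linear trend on the length of the most frequent insert did not even the split. Length selection of another form is not decided. Removing the trend on GC content took the split from 38 against 2 to 31 against 9, a ratio of 3.44 (1.60 to 8.23). The interval spans the bound of 3, so GC bias may be a part of the cause, and whether it is the whole is not decided. With 31 against 9 more calls stayed on the siSrf2 side, so removing the linear trend did not even the split. The intervals of these 3 ratios treat each miRNA as an independent draw. miRNAs of 1 cluster, read in 1 pair of libraries, need not be independent, so these intervals may be too narrow. On the main scale both removals had first given 58 and 57 against 1, but there the kept median fixes the outcome. Across 7622 inserts outside hairpins Spearman's rho of the log2 ratio with GC was -0.24, which met what GC bias predicted as first written, but 6154 of them match no genome sequence and rho over the 1468 that do was 0.05, a condition added after both were known. The mean insert was longer in the library labelled siSrf2 in 69.8% (60.1 to 78.4) of 106 miRNAs, between the bounds set (with intervals apart from 0, 46 were longer there and 5 in the library labelled siSrf1), and with 1 library per group a response to an siRNA cannot be told apart from a difference between library preparations.

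Reads of the duplex at position 1878 appeared 19 times in the library labelled siSrf1 beside 1230 in the library labelled siSrf2, and carry-over of library molecules or reads could be a cause. In the test written first, sense reads made up 94.7% (74.0 to 99.9) of them in the library labelled siSrf1 and 85.6% (83.5 to 87.5) in the library labelled siSrf2, intervals that overlap as carry-over predicts. A later test used sense reads of 19 and 20 nt, of which 20 nt made up 62.5% (35.4 to 84.8) of 16 reads and 20.0% (17.4 to 22.8) of 895, intervals that are apart. With 19 reads the interval of the first test is wide, so its overlap says little for or against carry-over. The later test goes against carry-over, but it rests on 16 reads that are not independent molecules, so carry-over stays open. No biological explanation was tested.

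miR-145a-5p (log2 ratio -2.29) lay far below miR-143-3p (-0.40), its neighbour on the minus strand of chromosome 18 (NCBIM37, 61807520 to 61807542 and 61808853 to 61808873), and below its own other arm, miR-145a-3p, with 84 and 89 reads (-0.30, interval -0.75 to 0.14). At 21 nt, the shortest length measured for both, they differed by -1.27 with intervals apart (-1.75, interval -2.45 to -1.14, against -0.48, interval -0.52 to -0.45), as they were at 22 nt (-2.05 against -0.26) and 23 nt (-2.34 against -0.08), which argues against length selection as the whole cause. After removal of the GC trend over 230 miRNAs miR-145a-5p lay at -2.12 (-2.26 to -1.99), below the 5th percentile of -1.86, the result predicted if GC bias was not the cause. This removal shifted no miRNA by more than 0.57, and miR-145a-5p was taken up for its far ratio, so the outcome was nearly fixed. It shows only that a linear GC trend leaves most of the ratio, and does not decide on GC bias of another form. Isoforms of 21 to 24 nt ranged over a log2 of 1.11, with a lower bound of 0.26, which met what selection of lengths or 3' ends predicted as first written, but an interval condition added after the value was known leaves it open, so such selection may contribute. A difference between the siRNAs also stays open as untested with 1 library per group. Of the labels' readings, the entry siNon for the library labelled siSrf2 goes against its 1230 reads of an Srf duplex. Which siRNA each library received is not settled.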
